A study of Homo sapiens with 8 samples.

How the data were processed

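Transcript levels were measured on 8 Affymetrix human GeneChip arrays, each hybridised with RNA from 1 cell sample. HT29 is an established human colorectal cancer line and Colo357 an established human pancreatic cancer line. The labels give 7 groups. HT29 untreated, HT29 treated with the anti-CD24 monoclonal antibody, Colo357 untreated, Colo357 treated with the antibody, an HT29 clone expressing a GFP-directed shRNA and an HT29 clone carrying 1 vector with a CD24-directed shRNA had 1 array each. HT29 clones carrying 2 such vectors had 2 arrays, one for each of 2 clones. The antibody was applied at a dilution of 1 to 40 for 72 h, per the labels' protocols.

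The deposited values are probe set intensities on a linear scale. They are MAS5 signals, per the submitters' processing notes, with a version that is not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common target. The mean after trimming 2% from each end was 250.1 on each of the 8 arrays, so the values were used as deposited, with no further scaling. Background handling and detection calls are not given in the sources used here, so no probe set was called absent. The table holds 22277 probe sets, of which 62 are controls. The platform annotation used here gave 1 gene symbol to 19064 probe sets, several to 1043 and none to 2108. Symbols were updated through the Entrez ID in the RefSeq gene table of the GRCh38.p14 assembly for 19058 of the single-symbol probe sets. Probe sets with several symbols were not named.

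Intensities were converted to log2(intensity + 10), 10 being the 25th percentile of all non-control values rounded to a whole number. The added 10 understates differences of dim genes, and all log2 differences are on this scale. Each gene was represented by its single-symbol probe set with the highest mean over the 8 arrays, which gave 11963 genes. A comparison used genes whose mean over its own arrays lay above the median of all non-control probe sets. For CD24, the mean over its 6 probe sets was used as well.

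The 3 CD24 shRNA clones were compared with 2 controls, parental HT29 and the GFP shRNA clone, by limma (version 3.58.1 in R 4.3.3; lmFit and eBayes), which left 3 residual degrees of freedom. The antibody was tested over both lines on 4 arrays with the line as a fixed block, which left 1 residual degree of freedom. Adjusted p-values are Benjamini-Hochberg values from these limma fits, and tests were two-sided. The SE given with a log2 difference is limma's moderated SE, which draws on the spread of all genes. In the antibody fit it rests on 10.4 degrees of freedom, of which 1 is residual. The labels do not say whether clones or arrays came from independent cultures, so p-values measure the spread between these samples only. Comparisons of 1 array with 1 array (antibody within a line, GFP clone against parental cells) have no test and no error. For those, genes at 2-fold or more were counted. The number of arrays limits the precision of every value. The self-test below shows what the fits could detect in simulated values with independent normal noise.

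The 24 gene lists and the rule for naming genes were fixed before the data were examined, and 587 of the 677 list symbols had a value. Lists with at least 5 members above the filter were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were the alternatives. In comparisons without a test, a list's median was placed among 10000 random lists of equal size matched on mean expression, as a description of those arrays. The genes named are CD24; for the shRNA clones, the 12 per direction with the smallest unadjusted p among genes at 2-fold or more whose 3 clones lay on one side of both controls, because fewer than 10 passed the adjusted test; for the antibody in each line, the 12 largest differences per direction; for both lines, the 10 per direction whose smaller difference of the 2 lines was largest; for the GFP clone and for 2 vectors against 1 vector, 5 per direction; and up to 4 members of a described list.

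The fits were tested on simulated log2 values with the real gene means, the moderated residual spread of the real fits and 200 changed genes. In the shRNA comparison, over 6756 genes, adjusted p under 0.05 recovered 0 of 50 genes changed 2-fold, 33 of 50 changed 4-fold and 50 of 50 changed 8-fold, and 10 of 6556 unchanged genes were called. That recovery did not carry over to the real shRNA fit, where genes beyond 8-fold such as CD24 (log2 difference -4.12) and SPRR1B (4.74) did not pass. A gene that failed there may still be changed 8-fold. In the antibody comparison, over 6787 genes, it recovered 20 of 50 changed 2-fold and 50 of 50 changed 4-fold, and 18 of 6587 unchanged genes were called. The alternatives tried were a doubled offset, values below the offset set to it, quantile normalization, no filter and a filter at the 75th percentile, the mean of a gene's probe sets, probe sets with the suffix _x_at left out, other fold thresholds, each single array left out of the shRNA fit, a fit of all 8 arrays, an intensity trend in the variance, an adjusted p combined with a 2-fold difference, and parental HT29 or single clones in the comparison of shRNA with antibody. An offset of 50, list tests against the GFP clone alone, and the CD24 mean without _x_at probe sets were added after seeing the data.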

Results

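The study asked how gene expression in cancer cells differs after CD24, a small glycosylated cell-surface protein, is lowered by shRNA or bound by a monoclonal antibody. The data are 8 arrays from 6 HT29 samples and 2 Colo357 samples. Only the group of HT29 clones with 2 CD24 shRNA vectors had 2 arrays, and every other group had 1. The median probe set intensity ranged from 32.4 in the first 2-vector clone to 63.1 in the GFP shRNA clone. Log2 values of all non-control probe sets correlated across probe sets at 0.96 between untreated and antibody-treated HT29, at 0.94 between the 2 Colo357 arrays and at 0.89 between untreated HT29 and untreated Colo357. Untreated HT29 correlated at 0.935 with the GFP clone, 0.897 with the 1-vector clone, and 0.889 and 0.944 with the 2-vector clones. The second 2-vector clone correlated at 0.960 with the GFP clone and 0.944 with the first 2-vector clone.

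CD24 itself was lower in all 3 CD24 shRNA clones. The mean log2 value over its 6 probe sets was 8.19 ± 0.35 (SD, n = 3) in the clones and 11.41 ± 0.22 (SD, n = 2) in parental HT29 and the GFP clone, a 9.29-fold difference. Its brightest probe set read 6425.1 in parental HT29 and 7362.5 in the GFP clone, against 558 in the 1-vector clone and 171.7 and 595.5 in the 2-vector clones. The mean log2 value was 8.40 in the 1-vector clone and 7.78 and 8.39 in the 2-vector clones. The probe sets differed in size, from 3.02-fold to 17.4-fold, the latter for the brightest. The exact two-sided permutation test gave p = 0.1, the smallest the 10 splits of 5 arrays allow, and limma gave adjusted p = 0.22 to 0.236 for the 6 probe sets. After antibody treatment CD24 was lower on all 6 probe sets in HT29, with a mean log2 difference of -0.41, and differed by 0.12 in Colo357 with probe sets on both sides of 0.

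**Figure D1:**
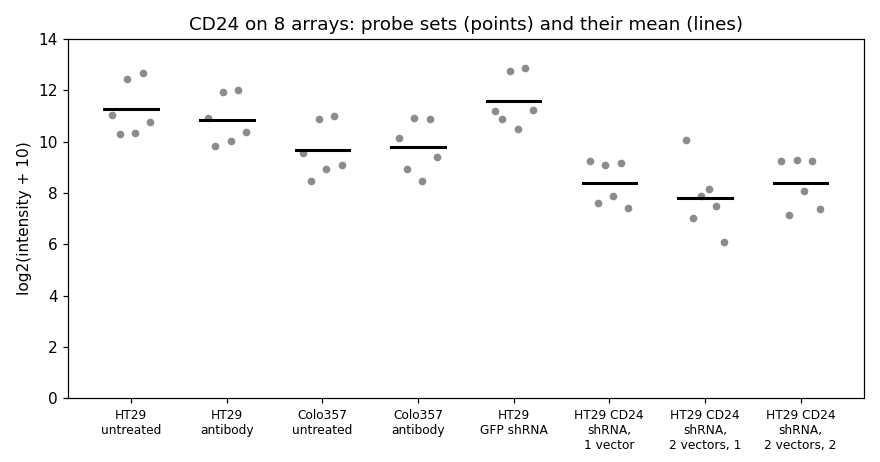
Log2(intensity + 10) of the 6 CD24 probe sets (points) and their mean (line) on each of the 8 arrays. The means of the 3 CD24 shRNA clones, 7.78 to 8.40, lie below those of parental HT29 (11.25) and the GFP shRNA clone (11.56).

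The second question was which other genes differed in the CD24 shRNA clones. Genes that were higher included ABCC8, the sulfonylurea receptor subunit of potassium channels (log2 difference 3.24 ± 0.55, SE), APOC1, an apolipoprotein (2.46 ± 0.45), HSD17B2, which oxidises estradiol (2.44 ± 0.54), and SPRR1B, a cornified envelope precursor (4.74 ± 1.08). SLC2A6, CITED1, ARC, SRPX, UBTD1, TGFB1I1, GAS2L1 and SMOX completed the 12 named genes in this direction, at 1.71 to 2.54. Genes that were lower included HSD17B8 (-3.13 ± 0.44), ATP1B1, the beta subunit of the sodium pump (-2.09 ± 0.37), the sialomucin CD164 (-3.05 ± 0.60), the procollagen lysyl hydroxylase PLOD2 (-2.18 ± 0.43) and the aldo-keto reductase AKR1B10 (-2.83 ± 0.57). CD24 stood among the 12 as well (-4.12 ± 0.56 for its brightest probe set), with SPAG1, RNF128, LACTB2, GCC2, LARP7 and TPMT at -1.80 to -2.49. Without _x_at probe sets TPMT was at -1.02 in place of -2.11, and with the mean of probe sets ABCC8 was at 1.60 and LARP7 at -1.14. None of these passed the limma test: each had adjusted p = 0.208, and n was 3 clones against 2 controls.

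Of 6756 genes above the filter, 0 passed adjusted p 0.05 in limma, while 1341 had an unadjusted p under 0.05 (431 higher, 910 lower), against 337.8 by chance. At 2-fold, 483 genes were higher and 1131 lower. The 3 clones lay on one side of both controls for 39.9% of genes, where chance gives 20% on average over splits of the arrays. The count was 587 (9 higher, 578 lower) without the second 2-vector clone and 85 (72 higher, 13 lower) without the GFP clone, which leaves parental HT29 as the lone control, assumed to vary like the other arrays. Against the GFP clone alone, likewise 1 array, 0 of 6771 genes passed and 886 had an unadjusted p under 0.05. The second 2-vector clone, whose removal gave 587 genes, had a lower dap 3′ spike control, described below, than the other 2 clones (405.5 against 916.9 and 667.5). Its mean CD24 value (8.39) was near that of the 1-vector clone (8.40), so the 587 genes cannot be assigned to CD24. The excesses over the chance values of 337.8 genes and 20% were not computed for other splits of these 5 arrays. Genes are not independent, and the same split separates the spike controls. These excesses cannot be assigned to CD24 either. Quantile normalization moved the median gene's difference from 0.04 to 0.18.

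Among the gene lists, 2 passed camera in the shRNA comparison. Interferon-stimulated genes were lower (median -1.08, 20 of 24 members negative, 12 at 2-fold or more; adjusted p = 0.0281, and adjusted p = 0.93 with an estimated correlation). IFI27 differed by -4.90 ± 1.16 (SE), IFIT1 by -2.46 ± 0.88 and the double-stranded RNA kinase EIF2AK2 by -2.30 ± 0.71, and 0 members passed limma over all genes or adjusted over the list alone. This list depended on the control. Against the GFP clone alone, a comparison of lists added after seeing the data, its median was -2.14, with 24 of 25 members negative and 20 at 2-fold or more. That arm is 1 array, so a difference of the group cannot be separated from a feature of that array. Against parental HT29 the median was 0.27, with 7 of 19 members negative. Mesenchymal genes were higher (median 0.89, 12 of 12 members positive; adjusted p = 0.0281, and adjusted p = 0.888 with an estimated correlation), with FN1, fibronectin, at 2.31 ± 1.29 and the matrix protein TNC at 2.26 ± 0.96, and 0 members past the test. This list also depended on the control: its median was 1.42 against parental HT29 and 0.37 against the GFP clone, where 9 of 13 members were positive. FN1 read 2.1 in parental HT29, 479.6 in the GFP clone and 471.8, 237 and 452.5 in the CD24 shRNA clones, so its difference came from parental HT29 alone.

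Other lists did not pass in the comparison with both controls. Heat shock genes had a median of -0.77 (10 of 13 negative; adjusted p = 0.11), with the HSP110-family member HSPA4L at -2.33 ± 0.65, CHORDC1 at -2.11 ± 0.53 and HSP90AA1 at -1.67 ± 0.65, and 2 members past the test adjusted over the list alone. NF-kB target genes had a median of 0.68 (adjusted p = 0.0892) and ERK output genes one of 0.52 (adjusted p = 0.161), with the ERK phosphatase DUSP5 at 2.78 ± 0.68. Cell cycle genes had a median of -0.22 (22 of 34 negative; adjusted p = 0.524). Intestinal differentiation genes had a median of -0.14, which turned to 0.18 under quantile normalization. The direction of several lists, interferon-stimulated genes among them, turned with the control. Cell cycle genes had a median of 0.28 against the GFP clone and -0.88 against parental HT29, and detoxification and NRF2 target genes had medians of 0.69 and -0.72, with -0.18 against both controls. Antigen presentation genes (-0.59 and 0.57) and Wnt target genes (-0.33 and 0.55) turned as well. Heat shock genes (-0.28 and -1.37) and NF-kB target genes (0.32 and 0.93) kept their direction but differed less against the GFP clone. Oxidative phosphorylation genes had medians of 0.36 and 0.11, and quantile normalization gave 0.13 against the GFP clone, below the 0.18 of all genes.

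The labels separate clones with 1 and 2 vectors. The receptor tyrosine kinase AXL read 13.2 in the 1-vector clone and 298.5 and 227.3 in the 2-vector clones. AKAP12 (134.4 against 1121.8 and 2344.7), NNMT (61.1 against 1013.2 and 568), SPRR1B and MAB21L4 were also higher with 2 vectors. SERPINA5 (1181.8 against 31.8 and 70.6), CREB3L1, LGALS4, CAMP and GJB1 were lower. At 2-fold or more, with the 1-vector clone outside both others, 403 genes were higher and 234 lower with 2 vectors. One array against one, the 2-vector clones differed from each other at 1365 genes, and the 1-vector clone differed from them at 568 and 1465. The count of 637 was 1477 (1163 higher, 314 lower) without the first 2-vector clone and 575 (233 higher, 342 lower) without the second, so the direction of the excess rests on single arrays. ERK output genes had a median of 0.46 (22 of 26 positive) and interferon-stimulated genes one of -0.43 (13 of 17 negative), at the 100th and the 0.06th percentile of random lists. There is no test of this comparison, and the first 2-vector array stands apart in RNA controls, with an 18S 3′ reading of 434.8 against 14.7 to 48 on the other arrays and an ACTB 3′ to 5′ ratio of 1.77 against 1.06 to 1.17.

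The GFP shRNA clone was compared with parental HT29 as a measure of how far an HT29 clone without CD24 shRNA lies from the line. The cancer-testis antigen MAGEA6 read 1659.5 in the clone and 13.7 in parental cells, IGFBP7 534.4 and 0.7, GABRP 1269.3 and 15.2, the bicarbonate transporter SLC4A4 1162.3 and 14, and AKAP7 537.3 and 3.2. In the CD24 shRNA clones MAGEA6 read 1.1 to 11.1, GABRP 3.5 to 58.2, SLC4A4 17.8 to 85 and AKAP7 30.5 to 81.3. IGFBP7 read 595.3 to 1119.7 there. In the other direction, E-cadherin (CDH1) read 15.4 in the clone and 2172.8 in parental cells, S100A4 67.5 and 7409, TM4SF4 61 and 5699, the retinaldehyde dehydrogenase ALDH1A1 86.4 and 4320.2, and KLK11 28.5 and 1285.9. These 5 lower genes read 271.9 or less in the CD24 shRNA clones. Interferon-stimulated genes had a median difference of 2.33, with 25 of 27 at 2-fold or more above parental cells, among them IFI27 (4.16), IFI6 (4.04) and OAS2 (3.97). Antigen presentation genes (median 1.35, 8 of 12 at 2-fold) and mesenchymal genes (1.73, 6 of 10) were higher as well. Cell cycle genes had a median of -1.08, with 19 of 35 at 2-fold or more below parental cells, including the phosphatase CDC25A (-3.74), thymidylate synthase TYMS (-2.45) and PLK1 (-2.11). Detoxification and NRF2 target genes had a median of -0.97, with 11 of 23 lower by 2-fold or more. Wnt target genes (0.79, 10 of 13 positive) and unfolded protein response and ATF4 target genes (0.56, 25 of 32) lay above the 99th percentile of random lists. The hypoxia and glycolysis list (0.04) and the intestinal differentiation list (0.03) turned negative under quantile normalization. In all, 966 of 6700 genes were higher and 473 lower at 2-fold, 21.5% of genes, and quantile normalization gave 809 and 694 (53.8% higher, in place of 67.1%) while moving the median gene from 0.09 to -0.05.

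**Figure D2:**
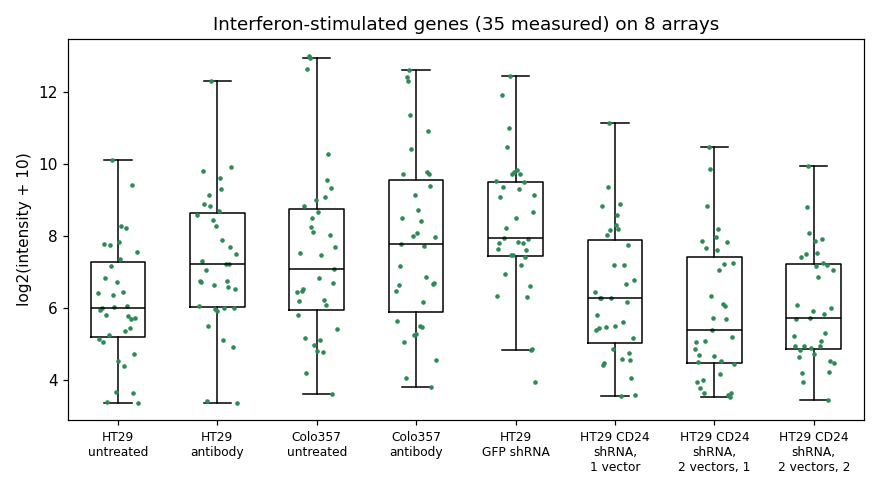
Log2(intensity + 10) of the measured interferon-stimulated genes (points, with box for quartiles and line for the median) on each of the 8 arrays. The GFP shRNA clone lies above parental HT29, with a median difference of 2.33 over the 27 members above the filter, and the 3 CD24 shRNA clones lie near parental HT29 in their median.

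Antibody treatment of HT29 was compared with untreated HT29, 1 array each. The NKG2D ligand ULBP2 read 235.8 after treatment and 9.3 before, CLIC3 911 and 90.2, the interleukin-1 receptor antagonist IL1RN 757.9 and 88.3, CYP1A1, a target of the aryl hydrocarbon receptor, 682.8 and 84, and PLAAT4 1334.3 and 184.2. LAT2, CYP4F12, EMP3, ALDOC, APOL1, SERPINE2 and MAOB were also among the 12 highest, at log2 differences of 2.54 to 3.22. The co-chaperone DNAJB6 read 13.2 after treatment and 290.4 before, the chloride channel CFTR 9.7 and 167.2, ASPM, a spindle protein, 37.3 and 247.7, and the transcription factors ETS2 333 and 1835.9 and MYB 101.8 and 569.6. ARFGEF1, LRBA, SLC19A1, SNORA21, FAM149A, CAPN15 and ADH1C completed the 12 lowest. At 2-fold, 337 of 6692 genes were higher and 489 lower (12.3%), fewer than the 1439 between the GFP clone and parental HT29. Quantile normalization gave 402 and 347, or 53.7% higher in place of 40.8%.

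In HT29 the interferon-stimulated genes stood out among the lists. Their median was 1.40, with 23 of 25 members positive and 15 at 2-fold or more, at the 100th percentile of random lists, and OASL (2.26), IFI6 (2.26) and ISG15 (2.20) were highest. Antigen presentation genes had a median of 0.71 (12 of 13 positive), with the peptide transporter TAP1 at 2.01. Intestinal differentiation genes had a median of 0.71 (14 of 17 positive, 7 at 2-fold), including KLF4 (1.87), KRT20 (1.84) and villin, VIL1 (1.66). Cholesterol synthesis genes had a median of 0.44 (16 of 20 positive), with TM7SF2 at 1.98. Wnt target genes had a median of -0.60, at the 0.235th percentile, with 6 of 13 positive; ETS2 (-2.43), SLC12A2 (-2.02), and LGR5 (-1.44) were lower while MMP7 was 1.36 higher. Unfolded protein response and ATF4 target genes had a median of -0.06, which turned to 0.05 under quantile normalization. The list medians are descriptions of 2 arrays, without a test.

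In antibody-treated Colo357 GDF15 read 2702.5 after treatment and 142.4 before, the transcription factors DDIT3 1445.1 and 84.5 and ATF3 1051.8 and 65.2, the EGF receptor ligand HBEGF 1925 and 117.9, the matricellular genes CCN1 1442.7 and 77.9 and CCN2 428 and 19.1, and TNF 322.8 and 19.2. G0S2, INHBE, TNFRSF12A, UPP1 and PLAU were the other 5 of the 12 highest, at 3.56 to 4.07. GDF15 rested on an _x_at probe set: without such probe sets its difference was 0.52 in place of 4.15. RARRES1 read 162 after treatment and 3398.9 before, HTRA1 12.9 and 337.3, SLC4A4 16.3 and 324.5, TM4SF20 140.9 and 1717.5 and IGFBP3 453.9 and 4171.2. ATXN10, ANK3, OPN3, CDK19, OBSL1, FTO and CPNE1 were the other 7, at -2.92 to -3.45. At 2-fold, 720 of 6829 genes were higher and 867 lower (23.2%), and quantile normalization gave 881 and 857, so the excess of lower genes depends on the scaling.

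ERK output genes had the largest list median in Colo357, 1.91, with 22 of 24 members positive and 16 at 2-fold or more, led by HBEGF (3.92), PHLDA1 (3.49), DUSP5 (3.43) and PHLDA2 (3.31). p53 target genes had a median of 0.99 (12 of 17 positive), with CDKN1A, the p21 cell cycle inhibitor, at 2.94 and GADD45A at 2.90, while CCNG1 was at -2.69. NF-kB target genes had a median of 0.76 (16 of 20 positive), with TNF at 3.51, IL1B at 3.15 and TNFAIP3 at 2.48. These 3 lists lay above the 99th percentile of random lists. Cell cycle genes had a median of -0.32 (25 of 35 negative, 11 at 2-fold), with CENPF at -2.43 and MKI67 at -1.99. All 24 ribosomal protein genes were negative (median -0.33), and quantile normalization moved that median to 0.00. Interferon-stimulated genes had a median of 0.18, with ISG15 at 3.10 and IFI27 at 2.00 but 10 of 26 members negative; whether this differed from HT29 was not tested.

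**Figure D3:**
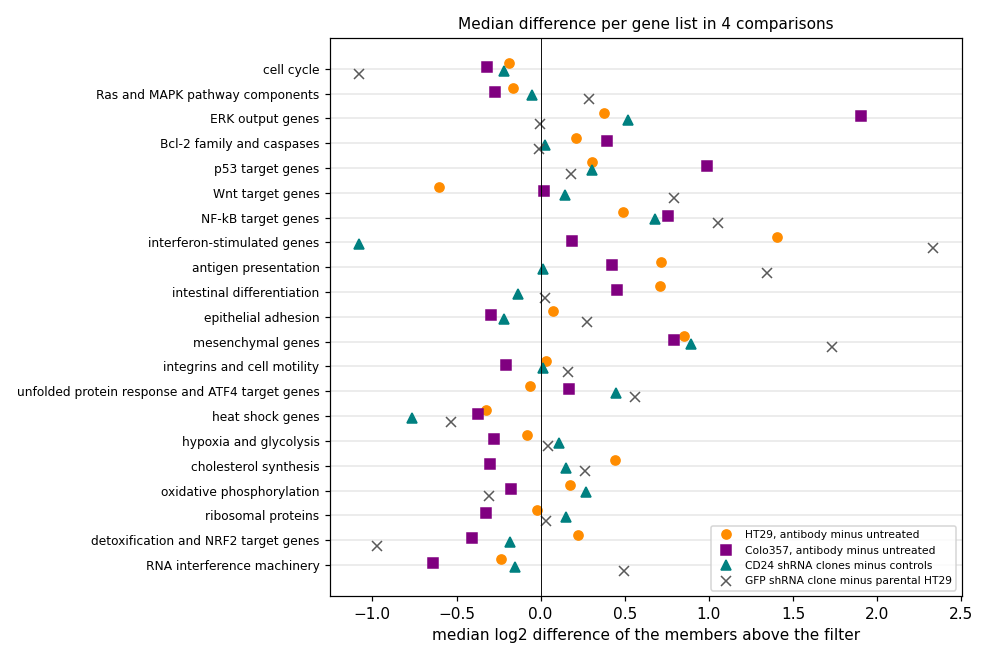
Median log2 difference of the members above the filter (x axis) for 21 gene lists (y axis) in 4 comparisons, given by symbol. ERK output genes in antibody-treated Colo357 (1.91) and interferon-stimulated genes in the GFP shRNA clone (2.33) lie furthest from 0.

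Both lines together allowed a test of what the antibody-treated arrays shared. RND1 (3.39 ± 0.32, SE, n = 2 lines; limma adjusted p = 0.00508), CYP1A1 (3.61 ± 0.39; 0.0089), CDKN1A (2.67 ± 0.33; 0.0101), the ubiquitin-like protein ISG15 (2.65 ± 0.35; 0.0107) and EMP3 (2.71 ± 0.33; 0.0101) rose. APOBEC3B, ULBP2, TUBB2A, IFI27 and ISG20 rose as well, at adjusted p = 0.0107 to 0.02. DNAJB6 (-3.13 ± 0.37; 0.0101), LRBA (-2.64 ± 0.32; 0.0101), ARFGEF1 (-2.57 ± 0.33; 0.0107) and ASPM (-2.47 ± 0.32; 0.0107) fell, as did DNAJC13, SF3B3, IRF2, PHIP, INPP5A and MBNL1. In all, 78 of 6787 genes rose and 165 fell at adjusted p 0.05. The fit has 1 residual degree of freedom, so each SE mostly reflects the spread pooled over genes, not that gene's 2 lines. Under quantile normalization, without the filter, or in a fit of all 8 arrays, 0 genes passed. No array of a control antibody was analysed here, and all differences are against untreated cells.

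Over both lines 7 lists passed camera, all upward, and each had adjusted p = 0.858 with an estimated correlation. With 1 residual degree of freedom that correlation is barely estimated, and it came out at 1 for ERK output genes. A list could hardly pass this alternative, so it does not decide. The camera p-values below rest in turn on the preset correlation of 0.01. For interferon-stimulated genes the estimate was 0.59 here and 0.73 in the shRNA fit, which had 3 residual degrees of freedom. These p-values may therefore be far too small. Interferon-stimulated genes had a median of 0.67 (26 of 27 positive; adjusted p = 5.6e-07), with 6 members past limma over all genes and 9 up and 1 down adjusted over the list alone; OASL rose by 2.08 ± 0.33 and TAP1 by 1.85 ± 0.33. ERK output genes had a median of 1.06 (21 of 25 positive; adjusted p = 1.0e-06), with 3 members past over all genes and 12 adjusted over the list alone, and HBEGF rose by 2.48 ± 0.55. Colo357 carried most of this: the ERK output median was 0.38 in HT29, with 3 of 26 members at 2-fold or more, and 1.91 in Colo357. The interferon median came mostly from HT29, at 1.40 against 0.18. Antigen presentation (median 0.53; adjusted p = 0.00128), NF-kB target (0.57; 0.00146), mesenchymal (0.51; 0.00146), p53 target (0.66; 0.00703) and intestinal differentiation genes (0.59; 0.0164) followed, with ICAM1 (1.86 ± 0.34), CXCL8 (1.69 ± 0.35), CCN1 (2.78 ± 0.51), THBS1 (1.80 ± 0.37) and KLF4 (1.59 ± 0.33) past the test over all genes. The lines differed here too. Intestinal differentiation genes had 14 of 17 members positive in HT29 but 8 of 15 in Colo357, where 4 were higher and 5 lower at 2-fold. The p53 target median was 0.30 in HT29 and 0.99 in Colo357. Among p53 target genes CCNG1 fell (-1.89 ± 0.41). Cell cycle genes did not pass as a list (median -0.26; adjusted p = 0.134), although CENPF (-1.88 ± 0.36) and BUB1B (-1.47 ± 0.33), both mitotic proteins, fell.

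**Figure D4:**
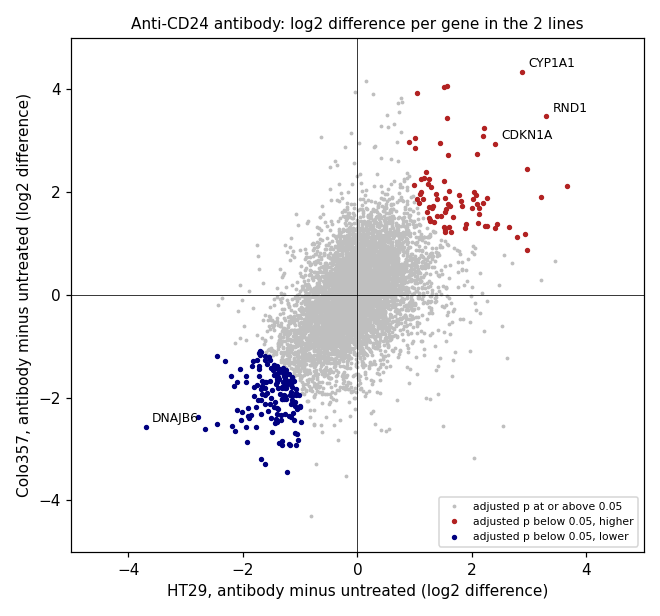
Log2 difference of antibody-treated minus untreated cells for each of 6787 genes in HT29 (x axis) and Colo357 (y axis), with genes past adjusted p 0.05 in the limma fit coloured. The 78 genes that rose and 165 that fell lie in the corners where both lines moved the same way.

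Antibody differences of the 2 lines correlated across genes at r = 0.51 (Spearman 0.51), on 4 arrays with none shared; genes are not independent replicates. At 2-fold, 111 genes were higher in both lines, where independent lists give 36.6, 266 were lower in both (58.6 for independent lists) and 21 went opposite ways (92.8). The shRNA difference, taken against the GFP clone so that no array was shared, correlated with the antibody difference at 0.31 in HT29 and 0.40 in Colo357. Of 6786 genes, 237 were lower at 2-fold in both the shRNA and the HT29 antibody comparison (92.6 for independent lists) and 396 in the shRNA and the Colo357 comparison (158.2). ARFGEF1 read 382.2 in the GFP clone and 36.8, 26.6 and 188 in the CD24 shRNA clones, MBNL1 736 against 53.9, 153.5 and 549, and PHIP 149.8 against 8.5, 11.1 and 66. The second 2-vector clone alone gave 0.09 with HT29 and 0.26 with Colo357.

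The 5 arrays with CD24 targeted also differed from the other 3 in the poly-A spike controls, bacterial transcripts added to the RNA before labelling. The dap 3′ control averaged 702 ± 221 (SD, n = 5) on the CD24-targeted arrays and 276 ± 1.2 (SD, n = 3) on untreated HT29, untreated Colo357 and the GFP clone (exact two-sided permutation p = 0.0536, adjusted p = 0.0804 over 6 controls). The thr, phe and lys 3′ controls differed 2.27-, 1.97- and 3.62-fold in the same direction. The hybridization controls bioB and cre, which are added after labelling, stood at 0.92 and 0.87 of the other arrays' mean. This split follows the antibody and CD24 shRNA groups exactly, so spike level and CD24 targeting cannot be told apart in any of the comparisons of these groups.

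**Figure D5:**
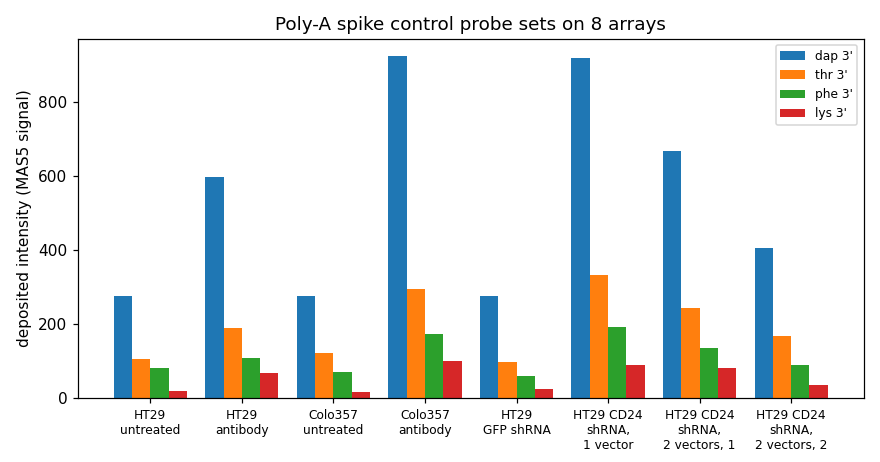
Deposited intensity of the 3′ probe sets of 4 poly-A spike controls (bars) on each of the 8 arrays. The dap 3′ bar is 274.8 to 277.1 on untreated HT29, untreated Colo357 and the GFP shRNA clone and 405.5 to 922.9 on the 5 arrays with CD24 targeted.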

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

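All tests of an explanation in this part were chosen after the results were seen. The dap 3′ poly-A spike control was 2.55 times as high on the 5 CD24-targeted arrays as on the other 3, a signal outside the gene measurements. The 18S ribosomal RNA 3′ control read 434.8 on the first 2-vector clone and 14.7 to 48 on the other 7 arrays, and the 3′ to 5′ ratio of ACTB was 1.77 there against 1.06 to 1.17 elsewhere.

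Antibody-treated and CD24 shRNA arrays differed from their controls in similar genes (r = 0.31 and 0.40 for HT29 and Colo357). A candidate explanation is a difference in RNA input or labelling, which the spikes would mark. The 1-vector clone and the second 2-vector clone have about equal CD24 (8.40 and 8.39) but dap 3′ values of 916.9 and 405.5. Their difference still correlated with the antibody difference, at 0.301 for Colo357 and 0.398 for HT29, which is what that explanation needs. This sets 1 array against 1 and restates the lower correlations of the second 2-vector clone, so it does not decide. The first 2-vector clone (dap 3′ 667.5) gave 0.314 with HT29 and 0.424 with Colo357, against 0.363 and 0.390 for the 1-vector clone. The order by spike level thus held for HT29 and not for Colo357. Lower readings of dim probe sets alone are argued against, since after quantile normalization, among genes above the 75th percentile, the correlation was 0.409 for Colo357 and 0.27 for HT29. An effect of losing or blocking CD24 stays open and cannot be told apart from the spike difference, because the lowest spike level of the CD24-targeted arrays was 1.46 times the highest of the others.

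Antibody differences went opposite ways in HT29 and Colo357 for 21 genes at 2-fold, and these differences between the lines were not tested. CYP4F12 was at 3.19 in HT29 and -1.99 in Colo357. APOL1 was at 2.62 and -1.23. MAOB was at 2.54 and -2.54. IGFBP3 was at 2.03 and -3.17. INHBE was at -1.06 in HT29, where it read 13.3 before and 1.2 after treatment, and at 3.99 in Colo357.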

How the results depend on the processing

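The lower CD24 level of the shRNA clones (-3.22) kept its direction under the alternatives run for it and moved by more than the SD between clones for the brightest probe set (-4.12) and without _x_at probe sets (-2.67, added after seeing the data). Genes past the test in the shRNA comparison stayed at 0 except when single arrays were left out, which gave 0 to 587. Genes past the test for the antibody in both lines (243) fell to 0 in the fit of all 8 arrays, without the filter and under quantile normalization, to 68 with the mean of probe sets, where MBNL1 no longer passed, and to 84 with the filter at the 75th percentile; fewer genes were tested in the last, and the other causes were not tested. The lists past camera (2 for shRNA, 7 for the antibody) were 0 with an estimated correlation and 0 with fry in both comparisons, and 4 for shRNA against the GFP clone alone, an arm of 1 array added after seeing the data, of which 0 passed with an estimated correlation and 0 with fry. For the antibody, the estimated correlation and fry rest on 1 residual degree of freedom, so a list could hardly pass either. Counts at 2-fold moved with the threshold and filter by construction. In HT29 with antibody (826), they were 2216 at 1.5-fold, 165 at 3-fold, 1557 without the filter, 290 with the 75th percentile filter and 453 with the added offset of 50. In Colo357 (1587), they were 3276, 496, 2422 and 758 under the first 4 of these, and for the GFP clone (1439) 2931, 538, 2454 and 638. For 2 vectors against 1 (637), they were 1690, 139, 1193, 231 and 327 under all 5, and 575 to 1477 with a 2-vector clone left out. The second 2-vector clone alone gave a correlation of 0.0904 with the antibody in HT29 and 0.257 in Colo357. With parental HT29 as the shared control the HT29 correlation was 0.386, where unchanged groups sharing that array gave 0.612 in simulation (covariance 0.29 observed, 0.362 simulated). The simulation gave all arrays the residual spread of the shRNA fit, antibody-treated HT29 included. Its values are therefore no baseline for arrays with less spread. Of the named genes' values under alternatives, 717 stayed, 24 passed the test where they had not (without the GFP clone or the second 2-vector clone), 21 no longer passed (20 of them under quantile normalization), 27 moved by over 1.5 times and 0 reversed, CD24 left apart. That tally leaves out the fit of all 8 arrays and the other filters, and all 20 genes named for both lines also lost their call in that fit and without the filter. The CD24 difference in antibody-treated Colo357 was 0.12 as the mean of probe sets and turned to -0.14 for the brightest probe set. No paired analysis was possible because the labels carry no replicate numbers shared between groups, apart from the pairing of treated and untreated arrays by cell line that the antibody fit uses as its block. Without detection calls, signal over background was not assessed, and genes below the filter were not used in counts.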

Other observations

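All tests of an explanation in this part were chosen after the results were seen, and so were the genes named in the next 2 sentences. All 4 shRNA clones, the GFP clone included, shared a set of genes set apart from both HT29 arrays: 48 of 6759 genes were at least 4-fold higher and 22 at least 4-fold lower in each clone than in each HT29 array. The higher genes included the tubulin TUBA1A (973 to 7246.9 in the clones, 30.6 and 22.2 in HT29), SEPTIN6 (279.6 to 539.7 against 3.4 and 2.8), the ciliary transcription factor FOXJ1 (268.4 to 595.6 against 11.7 and 6.6) and WWTR1, a Hippo pathway co-activator (169.6 to 1017.2 against 3.8 and 5.1), and the lower genes included CDH1 (1.4 to 15.4 against 2172.8 and 2209.7), ANXA10 (75.7 to 302 against 2276.7 and 2284.7) and BST2 (0.9 to 88.2 against 674.5 and 964.7). RNA interference machinery genes, which a vector-borne shRNA uses, had medians of -0.16 in the CD24 shRNA clones and 0.50 in the GFP clone (0.22 under quantile normalization), at the 31.8th and 90.8th percentile of random lists. Over both antibody-treated lines, which carry no shRNA, the list's median was -0.46 with 7 of 8 members negative (camera adjusted p = 0.071). The processing enzyme DICER1 was lower in antibody-treated HT29 (-1.29) and Colo357 (-0.82).

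A spike-linked labelling difference is argued against as the source of the distance between the GFP clone and parental HT29, because the dap 3′ control of that clone was 0.993 of that of parental HT29. For the CD24 shRNA clones over all genes it cannot be told apart from the clones themselves. Even the lowest of the 3 had 1.46 times the dap 3′ value of parental HT29. Antibody-treated HT29 had a dap 3′ value of 595.9, against 405.5 in the second 2-vector clone. It still lay nearer to parental HT29 in 89.8% of the genes at 8-fold between that line and the GFP clone. On this 1 array a high spike level did not bring that shift. Independent drift of single clones is argued against for a part of the distance only. All 3 CD24 shRNA clones lay nearer to the GFP clone in 51 (58.0%) of the 88 genes at 8-fold between the GFP clone and parental HT29. In the other genes they did not all do so, and drift of single clones stays open there. A shared subclone of HT29, selection for the vector, and clones and parental array from different source cells may each give the 70 shared genes and cannot be told apart, because no other array of the source cells was used here.

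Interferon-stimulated genes were higher in the GFP clone than in parental HT29 (median 2.33, quartiles 1.65 and 3.08). A response of this size to shRNA vectors in general is argued against. The CD24 shRNA clones carry such vectors, yet the same 27 genes had a median of -0.0074 (quartiles -0.64 and 0.43) in them against parental HT29. A smaller response stays open, since the 19 members above the filter in that comparison had a median of 0.27. These clones also differ from parental HT29 in CD24 and spike level, which this comparison does not separate. A spike-linked labelling difference is argued against as well, since the dap 3′ control of the GFP clone was 0.993 of that of parental HT29. Array differences that the spikes do not mark were not tested. The low interferon median of the CD24 shRNA clones may therefore be set by the GFP array, as it was 0.27 against parental HT29 alone (19 members). This does not hold for every member. Of the 27 genes, 14 were below parental HT29 in these clones. IFI27 read 208.7 in parental HT29 and 67.1, 3.6 and 18.3 in the CD24 shRNA clones. Whether the GFP shRNA, the GFP clone or its culture gave the high readings of the GFP array stays open with 1 array.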
